A study of Homo sapiens with 10 samples.

How the data were processed

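Total RNA from 5 lines of MDA-MB-231 cells was measured on Affymetrix expression arrays, 2 arrays per line. One line was the cultured parental cells, which the labels call sensitive to SM-164. The other 4 lines were tumour cells isolated from xenografts that had shrunk under SM-164 in SCID mice and then regrown; the labels call T2 and T3 resistant and T6 and T8 sensitive. The drug had been given intravenously at 5 mg/kg on 5 days a week over 2 weeks, and labelling started from 5 ug of total RNA.

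The deposited table holds log2 expression values made by the authors, 1 column per array and 54675 probe sets. Affy, RMA and limma are named for it per the submitters' processing notes, without versions or settings. RMA is a method that corrects background, quantile-normalises probes over arrays and summarises each probe set by median polish. No detection filter had been applied, since every probe set had a value on every array. The values ran to a highest log2 value between 14.7 and 14.8 on each array, with medians of 5.43 to 5.57. An array has no read depth, so the number of arrays and the distance of a signal from background limit the precision.

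Probe sets were named through the platform annotation supplied with the values. Of the 54675 probe sets, 62 Affymetrix controls were left out, 41091 had 1 gene symbol, 1801 had several and 11721 had none; for 41037 the symbol was brought up to date by Entrez number against the RefSeq gene table of GRCh38.p14. The start and end positions in that table also gave the order of neighbouring genes and the bounds of the stretch from HLA-F to HLA-DPB1. The probe set with the highest mean over all arrays stood for its gene, without regard to group, which gave 19775 genes. A gene was tested if that probe set reached log2 5 on at least 2 arrays, leaving 14929 genes. Probe sets with several names or none were tested apart from the rest.

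Comparisons were fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The response (resistant minus sensitive) was tested on the mean of each line's arrays, with the tumour as the replicate and the parental line as a class of its own, which left 2 residual degrees of freedom between lines and a prior of 2.73. A model with 1 coefficient per line over all 10 arrays, with 5 residual degrees of freedom and a prior of 9.39, gave the same contrast for these particular tumours, the mean of the 4 tumours against parental cells, each tumour against parental cells, T2 against T3 and T6 against T8. A p-value of that model measures the spread between the arrays of a line. Changes are log2 differences with the standard error (SE) of the moderated fit.

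The tests, the gene lists, the named genes and the alternatives were fixed before the data were examined, apart from those said to have been chosen later. Named genes were 12 fixed genes given whatever they showed, of which 10 were measured and 2 were not analysed here. For the response, the 12 largest differences per direction were named among genes called with the tumour as replicate and with every resistant array on one side of every sensitive array; since none passed, the places were filled by the same rule from the fit over arrays. For the tumours against parental cells, the 12 largest mean differences per direction among genes called the same way in each tumour were named, and for each single comparison the 3 largest per direction. Of a described gene list, the called members with the largest changes were named, or, where none was called, the 2 with the largest changes. Genes named outside these rules are said to be so.

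The 35 gene lists covered cell death (IAP proteins and their antagonists, the TNF receptor complex, death ligands and receptors, the BCL2 family, caspases and the apoptosome), signalling (NF-kB targets, the LRIG family, receptor tyrosine kinases, EGFR ligands, ERK output and feedback, Wnt targets, TGF-beta targets, YAP and TEAD targets), immunity (interferon response, antigen presentation class I and class II), cell state (proliferation, epithelial markers, mesenchymal markers, genes described in metastatic MDA-MB-231 sublines, breast stem and luminal markers, cancer-testis antigens), stress and metabolism (hypoxia and glycolysis, p53 targets, unfolded protein and amino acid stress, heat shock and immediate early genes, cholesterol synthesis, NRF2 targets, drug efflux transporters, metallothioneins) and markers of other cells (macrophages, endothelium, fibroblasts and pericytes, blood and lymphocytes, adipocytes and muscle). Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, again with an estimated correlation, and with fry. Member calls were counted over all genes tested and adjusted over the list alone.

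Calls shared by the 4 tumours were set against 100 simulations of unchanged groups that kept the parental arrays in common, and against the overlap of independent lists. The 2 parental arrays were also split, 1 for 2 tumours and 1 for the other 2, in each of the 6 ways, with the spread taken from the tumours' arrays. Before use, the fits were tested on simulated data with the real genes' means and spreads and 200 changed genes among 14929. With the tumour as replicate, 7.69% of changes of log2 0.5 were called, 80.9% of log2 1 and 95.5% of log2 2, with 8 false calls. The response over arrays gave 98.5%, 100% and 100% with 8 false calls, the 4 tumours against parental cells 95.0%, 100% and 100% with 9, T2 against parental cells 75.0%, 100% and 100% with 19, and T2 against T3 77.6%, 98.4% and 100% with 15. No simulated change was called in the wrong direction. The simulated noise was independent between genes and took the moderated spreads as the true ones. These shares may therefore be higher than in the real data, above all with the tumour as replicate.

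Alternatives were a repeated quantile normalisation, array medians centred on a common value, no filter, a filter at log2 6, the mean over a gene's probe sets, leaving out probe sets of the types that can match several transcripts or genes, no trend, array weights, the replicate number as a block, a minimum change of log2 1, each array left out in turn and, for the response, other ways of treating tumours and arrays. A fit with the numbers of T2 and T3 exchanged and the split of the parental arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.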

Results

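Gene expression was measured in MDA-MB-231 cells, an established line from a human triple-negative breast cancer, before and after growth as xenografts under SM-164. SM-164 is a Smac mimetic, an antagonist of the IAP proteins that restrain caspases and cell death signalling from the TNF receptor. The series held 10 arrays. Of these, 2 measured the cultured parental cells and 2 each the cells of 4 regrown tumours. Tumours T2 and T3 are labelled resistant to the drug and T6 and T8 sensitive. Between 14096 genes (T8 replicate 1) and 14640 genes (T2 replicate 1) of the 19775 present before the filter reached log2 5 on an array. The labels do not say that the arrays of a line came from separate cultures, so p-values over arrays measure only the spread between these arrays, which may be technical. Arrays of a line correlated at 0.996 to 0.998 over genes and arrays of different lines at 0.972 to 0.995. The parental arrays stood apart on the leading principal component, at -34.3 and -40.2, while the tumour arrays lay between -3.79 and 18.6. The next component did not follow the response. T2 (-24.3 and -24.7) and T6 (-13.3 and -12.8) lay on one side, T3 (20.5 and 23.6) and T8 (6.41 and 6.84) on the other.

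**Figure D1:**
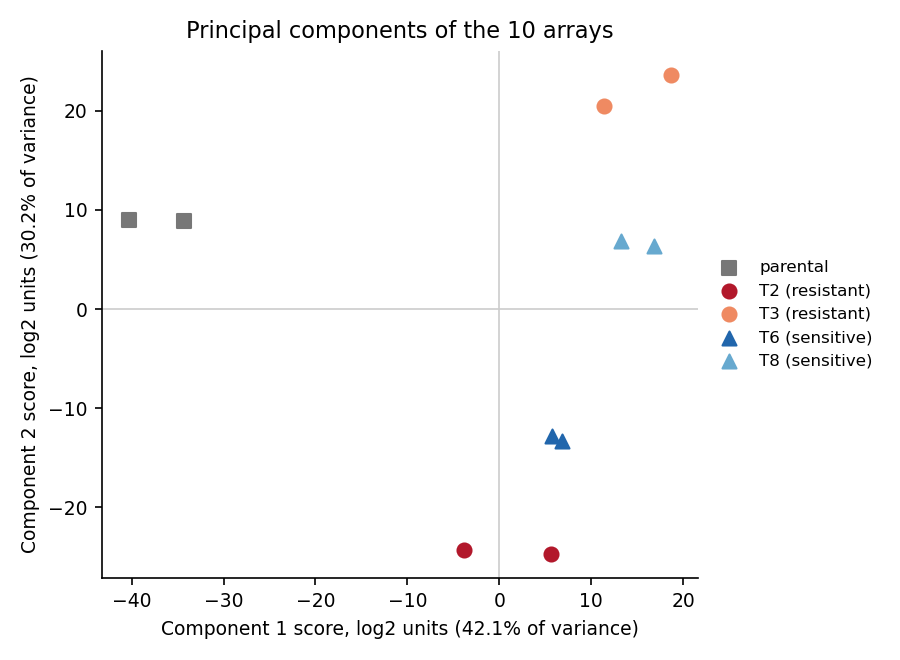
Scores of the 10 arrays on the leading principal components of the genes tested, in log2 units, with component 1 (42.1% of the variance) on the horizontal and component 2 (30.2%) on the vertical axis; each point is an array, coloured by line. The parental arrays sit at -34.3 and -40.2 on component 1, and component 2 places the resistant tumours T2 and T3 at opposite ends.

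The comparison of resistant with sensitive tumours asked which genes differ between tumours that regrew with and without loss of response. Over the arrays of these 4 tumours, PLCB4, a phospholipase C, rose by 2.36 ± 0.12 on the log2 scale (SE, 4 arrays against 4; adjusted p = 4.41e-08). Its means were 6.35 in T2 and 7.46 in T3 against 4.43 in T6, 4.67 in T8 and 4.27 in parental cells. The last 3 lie below log2 5, near background, where an array compresses differences, so the size of this one is uncertain. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, was higher by 1.76 ± 0.09 (adjusted p = 2.74e-08). Most of that came from T3 (9.14), beside 6.64 in T2, 6.07 in T6, 6.19 in T8 and 4.03 in parental cells. SPARC, a secreted glycoprotein that modulates cell contact with the matrix, fell by 1.79 ± 0.10 (adjusted p = 9.42e-08). It stood at 7.12 in T6 and 6.80 in T8 but at 5.34 in T2, 4.99 in T3 and 4.85 in parental cells. The atypical cadherin FAT3 showed the largest difference downward, -1.92 ± 0.09 (adjusted p = 2.01e-08). LRIG1, a membrane protein that restrains EGFR family and other receptor tyrosine kinases, differed by -1.01 ± 0.10 (adjusted p = 1.84e-05). LRIG1 means were 6.54 in T2 and 6.82 in T3 against 7.57 in T6, 7.80 in T8 and 7.51 in parental cells.

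Also higher in the resistant tumours were SPOCK1 (1.37), which encodes a secreted proteoglycan, GKN2 (1.34), the retinoic acid receptor gene RARB (1.19), ARHGAP20 (1.11) and the tubulin ligase gene TTLL11 (0.99). Smaller rises were seen in SDR16C5 (0.90), SMIM31 (0.79), DNER (0.79), the stromelysin gene MMP10 (0.74) and DPH5-DT (0.62). Lower were DCLK1 (-1.46), KCTD4 (-1.33), VSTM1 (-1.31) and TNFRSF11B (-1.29), which encodes a decoy receptor for TRAIL and RANK ligand. CDH5 (-1.27), ARHGAP30 (-1.12), COXFA4L3 (-1.09), the Rac activator TIAM1 (-1.07) and RGS7 (-1.04) fell too. CDH5, the cadherin of endothelial junctions, lay near background in every line (3.35 to 5.16). The SEs of these genes were 0.06 to 0.15 and their adjusted p-values at most 0.00236. Further probe sets went the other way for LRIG1 (0.26) and for TTLL11 (-0.17 and -0.09). LRIG1 and SPARC had no tested value once the less specific probe sets were left out, so that check is missing for them. With the mean over its probe sets LRIG1 stood at -0.24 (adjusted p = 0.0281, in a range of 3.07e-06 to 0.0281 over the other 18 alternatives). That mean also lowered RARB to 0.40, ARHGAP20 to 0.69, TTLL11 to 0.24, SPARC to -1.10, DCLK1 to -0.61, ARHGAP30 to -0.39, TIAM1 to -0.59 and RGS7 to -0.42. Each of these 8 genes was still called (adjusted p of at most 0.00878).

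With the tumour as the replicate, limma called 0 of 14929 genes, with 661 at an unadjusted p under 0.05 and a smallest adjusted p of 0.894. LRIG1 then stood at -1.01 ± 0.16 and SPARC at -1.79 ± 0.17 (adjusted p = 0.894 for both). The named differences therefore rest on array spread and describe these tumours alone. With so few tumours per class, 0 calls do not show that the classes are alike. Treating the line as a random block over arrays gave 4 genes, chosen for mention after their values were seen. They were SPARC (adjusted p = 0.00743), PLCB4 and SPOCK1 (0.0355 each) and TGFBR2 (0.0457), a TGF-beta receptor gene at -0.63. That fit used 1 correlation of 0.508 for all genes, so the arrays of a line still counted in part as separate replicates. Its 4 calls therefore do not replace the test with the tumour as replicate. Taking the 8 tumour arrays as independent gave 12 genes. Leaving out tumour T2 gave 23 genes and leaving out T3 gave 1, with 1 resistant tumour left and the spread taken from the sensitive pair alone. Over arrays 711 genes were higher and 2126 lower in the resistant tumours, 14 and 18 of them by at least log2 1. A repeated quantile normalisation split the calls 1428 to 1559, 47.8% higher in place of 25.1%, and centred medians split them 352 to 1828, 16.1% higher. Without T3 replicate 1 the count of 2837 fell to 1582, without T6 replicate 1 to 1559, without T6 replicate 2 to 1389 and without T8 replicate 1 to 1522.

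**Figure D2:**
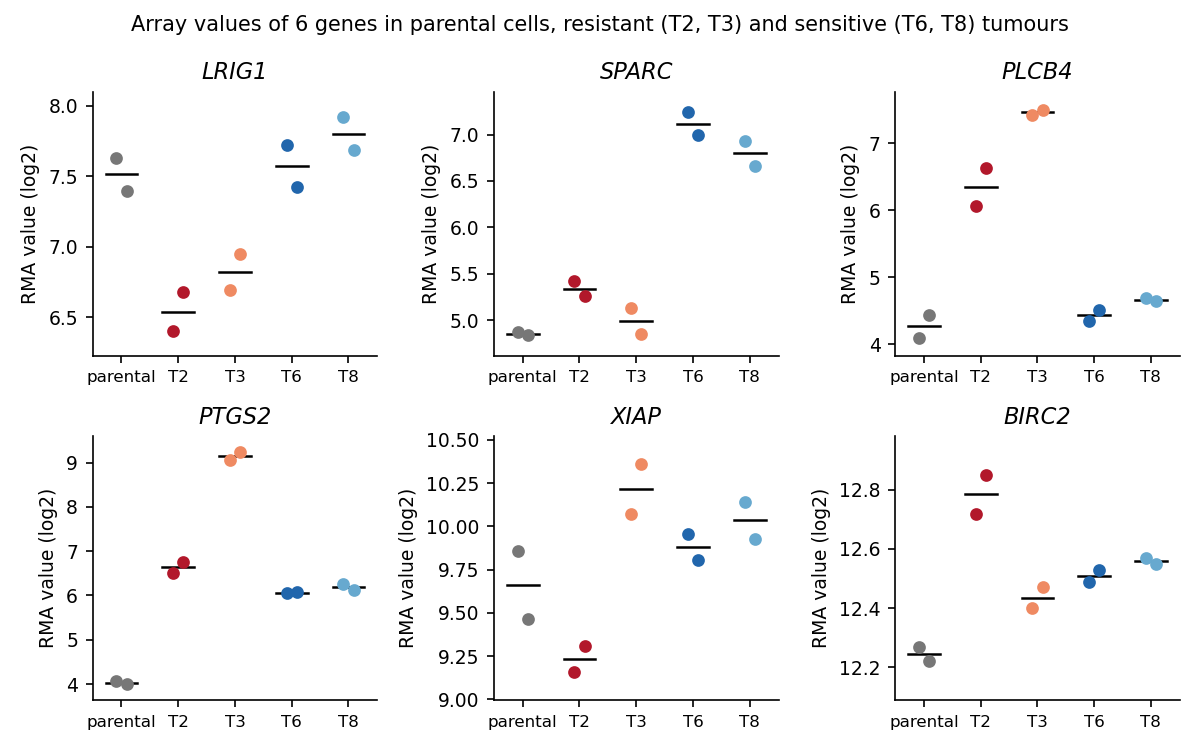
RMA values (log2, vertical axes) of LRIG1, SPARC, PLCB4, PTGS2, XIAP and BIRC2 on each array (points) with the mean of each line (bars), for parental cells, resistant tumours T2 and T3 and sensitive tumours T6 and T8 (horizontal axes). SPARC stands at 7.12 in T6 and 6.80 in T8 and at 5.34 or below in the other lines, whereas XIAP differs between the resistant tumours by -0.98.

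Of the 35 gene lists, 4 passed camera between resistant and sensitive tumours with the tumour as replicate, although no member was called over all genes. Antigen presentation class I was lower (0.0248, and adjusted p = 0.785 with an estimated correlation), with the immunoproteasome subunits PSMB9 at -0.44 ± 0.11 and PSMB8 at -0.44 ± 0.15. Cholesterol synthesis was lower as well (0.0314, and adjusted p = 0.785 with an estimated correlation), with NSDHL at -0.38 ± 0.29 and IDI1 at -0.31 ± 0.13. Markers of blood and lymphocytes were higher (0.0158, and adjusted p = 0.785 with an estimated correlation), with CD3E at 0.30 ± 0.10 and HBB at 0.29 ± 0.10. Markers of adipocytes and muscle were higher too (0.0321, and adjusted p = 0.785 with an estimated correlation), with DES at 0.37 ± 0.09 and PLIN1 at 0.29 ± 0.12. Host cells of these xenografts would be mouse cells, and the binding of mouse transcripts to the probes could not be tested. Changes in markers of other cells, here and below, therefore cannot be read as host cells. Repeated quantile normalisation ended the calls of cholesterol synthesis (0.0883) and of adipocytes and muscle (0.0933). Without a filter adipocytes and muscle (0.0784) and with a filter at log2 6 cholesterol synthesis (0.0586) were not called. All 4 calls ended with the mean over probe sets (0.0591 to 0.0990) and without the less specific probe sets (0.0620 to 0.563). Without T3 replicate 1 all 4 calls ended (0.0717 each). Without T2 replicate 1 cholesterol synthesis and blood cells (0.0726 each) and adipocytes and muscle (0.247) were lost, the last also without T6 replicate 1 (0.0710) and T8 replicate 1 (0.0926). Over 19 alternatives the adjusted p of these lists ran from 0.00517 to 0.785.

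The other 31 lists had adjusted p-values of 0.113 to 0.966. Adjusted over the list alone, LRIG1 was called in the LRIG family with the tumour as replicate. So were 1 lower gene each among endothelial and mesenchymal markers and 1 higher and 1 lower gene of the metastasis list. Fry called only the LRIG family (adjusted p = 0.0214). Camera called it without T2 replicate 2 (0.0487), and epithelial markers, higher, and class II genes, lower, without T8 replicate 1 (0.0435 each). Over arrays, class I genes were again lower, 5 of 17 over all genes and 6 adjusted over the list alone, with none higher (0.0248, and adjusted p = 0.807 with an estimated correlation). Cholesterol synthesis was lower in 8 of 18, also when adjusted over the list alone (0.0449, and adjusted p = 0.857 with an estimated correlation). Epithelial markers were higher in 6 of 26 and lower in none, or 6 and 2 adjusted over the list alone (0.0248, and adjusted p = 0.563 with an estimated correlation), led by the keratins KRT14 at 0.56 ± 0.12 and KRT19 at 0.44 ± 0.04. Markers of blood and lymphocytes were higher in 2 of 6, also when adjusted over the list alone (0.0473, and adjusted p = 0.686 with an estimated correlation). Markers of other cells went both ways over arrays in lists that camera did not call. Of 11 endothelial genes, PECAM1 (0.34 ± 0.08) and VWF (0.29 ± 0.09) were higher in resistant tumours. CDH5 (-1.27 ± 0.11), ENG (-0.69 ± 0.09), TIE1 (-0.41 ± 0.12) and ROBO4 (-0.38 ± 0.06) were lower (camera adjusted p = 0.471). Of 7 macrophage genes, AIF1 (0.38 ± 0.10) was higher and LAPTM5 (-0.74 ± 0.05) and CD14 (-0.37 ± 0.09) were lower (0.856). Of 7 genes of fibroblasts and pericytes, RGS5 (0.39 ± 0.10) and ACTA2 (0.38 ± 0.09) were higher and none lower (0.160).

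The comparison of the tumours with parental cells asked what cells that had grown, shrunk and regrown in mice had in common. No xenograft without SM-164 was measured. Growth in mice, the drug, the isolation of the cells and traits of the single parental line therefore cannot be told apart here. MMP1, an interstitial collagenase, rose by 4.52 ± 0.06 (SE, 8 arrays against 2; adjusted p = 3.64e-16), from 9.11 in parental cells to between 13.2 and 14.0 in the tumours. KISS1, the kisspeptin gene and a metastasis suppressor in other cancers, was higher by 3.37 ± 0.06 and EREG, the EGFR ligand epiregulin, by 3.14 ± 0.11. SERPINA1, the antitrypsin gene, fell by 3.54 ± 0.12 (adjusted p = 1.19e-11). The class II genes HLA-DPA1 (-3.37 ± 0.12) and HLA-DRA (-2.96 ± 0.12) and CD74 (-2.69 ± 0.11), the class II invariant chain, fell as well. TNFSF10, which encodes the death ligand TRAIL, stood at -2.46 ± 0.08.

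The other genes that rose most in all 4 tumours were NRK (3.44), a kinase gene, WDR72 (3.06), SEL1L3 (3.06), PTGS2 (2.98) and TENM3 (2.93). They were followed by the urea transporter SLC14A1 (2.79), the anti-apoptotic BCL2A1 (2.75), the axon guidance receptor ROBO1 (2.71) and the hyaluronan synthase HAS2 (2.61). The hyaluronan-degrading CEMIP (-3.39) fell, as did OLFML2A (-3.06), the cytochrome P450 gene CYP1B1 (-2.87) and the aldo-keto reductase AKR1C3 (-2.69). So did the water channel AQP1 (-2.59), STMN3 (-2.51) and ADGRF1 (-2.46). The SEs of all 24 were 0.06 to 0.14, and each adjusted p was at most 3.81e-09. For TENM3 the other probe set gave -0.12 (adjusted p = 0.511, the end of a range from 1.86e-13 over 19 alternatives), so its rise rests on 1 probe set. The mean over probe sets lowered TENM3 to 0.97, NRK to 2.12, EREG to 1.85, WDR72 to 1.13, SEL1L3 to 1.34, SERPINA1 to -2.00, CEMIP to -2.10, CD74 to -1.37 and ADGRF1 to -1.56. Without the less specific probe sets CEMIP stood at -0.81. All of them but TENM3 without the less specific probe sets were still called (adjusted p of at most 1.39e-05). In all, 3801 genes were higher and 2513 lower, 266 and 131 by at least log2 1. The share of higher calls moved with scaling, from 60.2% to 48.3% (3268 and 3501) with repeated quantile normalisation and to 71.9% (4084 and 1597) with centred medians. Without parental replicate 2 the count fell from 6314 to 4099.

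Gene lists separated into those lower and those higher in the tumours, with SEs of 0.04 to 0.17 for the members named. Of 17 measured genes of antigen presentation class I, 14 fell and none rose, also when adjusted over the list alone. The camera adjusted p was 2.19e-10, and adjusted p = 0.243 with an estimated correlation. Among them were PSMB9 (-1.40), the class I transactivator NLRC5 (-1.15) and HLA-B (-1.06). Of 12 class II genes 8 fell, or 10 adjusted over the list alone (9.91e-08, and adjusted p = 0.091 with an estimated correlation). HLA-DRB1 stood at -1.72, while CIITA, their transactivator, was not called (-0.18 ± 0.13). Of 38 interferon response genes 20 fell and 5 rose, or 23 and 5 adjusted over the list alone (0.000291, and adjusted p = 0.474 with an estimated correlation). SAMD9L was at -1.75 and RSAD2 at -1.43, against OAS1 at 1.15 and IFITM1 at 0.68. Targets of NRF2, the oxidative stress regulator, fell in 10 of 18 and rose in 2, also when adjusted over the list alone (0.0129, and adjusted p = 0.474 with an estimated correlation). AKR1C3, AKR1C1 (-1.38) and AKR1C2 (-1.18) led them, with NQO1 at -0.83 and the cystine transporter SLC7A11 at 0.81. Metallothioneins fell in 6 of 9, also when adjusted over the list alone (0.0129, and adjusted p = 0.474 with an estimated correlation), though by little (MT1E -0.33, MT1G -0.20). Macrophage markers fell in 3 of 7, also when adjusted over the list alone (0.0389, and adjusted p = 0.672 with an estimated correlation). These were CSF1R (-0.68), LAPTM5 (-0.61) and ITGAM (-0.40).

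Genes described in metastatic MDA-MB-231 sublines rose in 17 of 26 and fell in 6, or 17 and 7 adjusted over the list alone (0.000358, and adjusted p = 0.474 with an estimated correlation). They ran from MMP1, EREG and PTGS2 to the kynureninase KYNU (2.51) and the chemokine receptor CXCR4 (2.10), with ADIRF at -1.97. ERK pathway output rose in 11 of 22 and fell in 2, or 12 and 2 adjusted over the list alone (0.0129, and adjusted p = 0.672 with an estimated correlation). EGR1, an immediate early transcription factor, rose by 2.25, the ERK phosphatase DUSP6 by 0.86 and SPRED2 by 0.81. Heat shock and immediate early genes rose in 8 of 17 and fell in 1, also when adjusted over the list alone (0.0290, and adjusted p = 0.672 with an estimated correlation). EGR1 and the phosphatase DUSP1 (1.93) are immediate early genes, whereas the heat shock protein gene HSPB1 was lower (-0.59). NF-kB targets rose in 15 of 33 and fell in 7, or 16 and 7 adjusted over the list alone (0.0453, and adjusted p = 0.672 with an estimated correlation). PTGS2, BCL2A1 and the chemokines CXCL3 (1.93), CXCL1 (1.69) and CXCL8 (1.64) were above, the adhesion molecule VCAM1 (-0.97) below.

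Some of these list calls depended on processing or on 1 array. Repeated quantile normalisation ended the calls of heat shock genes (0.137, in a range of 0.000724 to 0.672 over alternatives) and macrophage markers (0.138, in a range of 0.00714 to 0.672). Centred medians ended that of metallothioneins (0.0622, in a range of 0.00130 to 0.683). A filter at log2 6 ended the calls of ERK output (0.0533, in a range of 0.00130 to 0.672), heat shock genes (0.0726) and NF-kB targets (0.0685). Macrophage markers were not called without a filter (0.0984), nor NF-kB targets with the mean over probe sets (0.138). Without the less specific probe sets the calls of NRF2 targets (0.477, in a range of 0.000356 to 0.477), metallothioneins (0.683), heat shock genes (0.0999), macrophage markers (0.168) and NF-kB targets (0.212) ended. Heat shock genes and macrophage markers were not called without parental replicate 2 (0.0872 each), nor were macrophage markers without T2 replicate 2 (0.0567) or T3 replicate 2 (0.0554). NF-kB targets were not called without parental replicate 2 (0.0599), T3 replicate 1 (0.0573), T3 replicate 2 (0.0554) or T8 replicate 1 (0.0504), in a range of 0.000370 to 0.672.

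**Figure D3:**
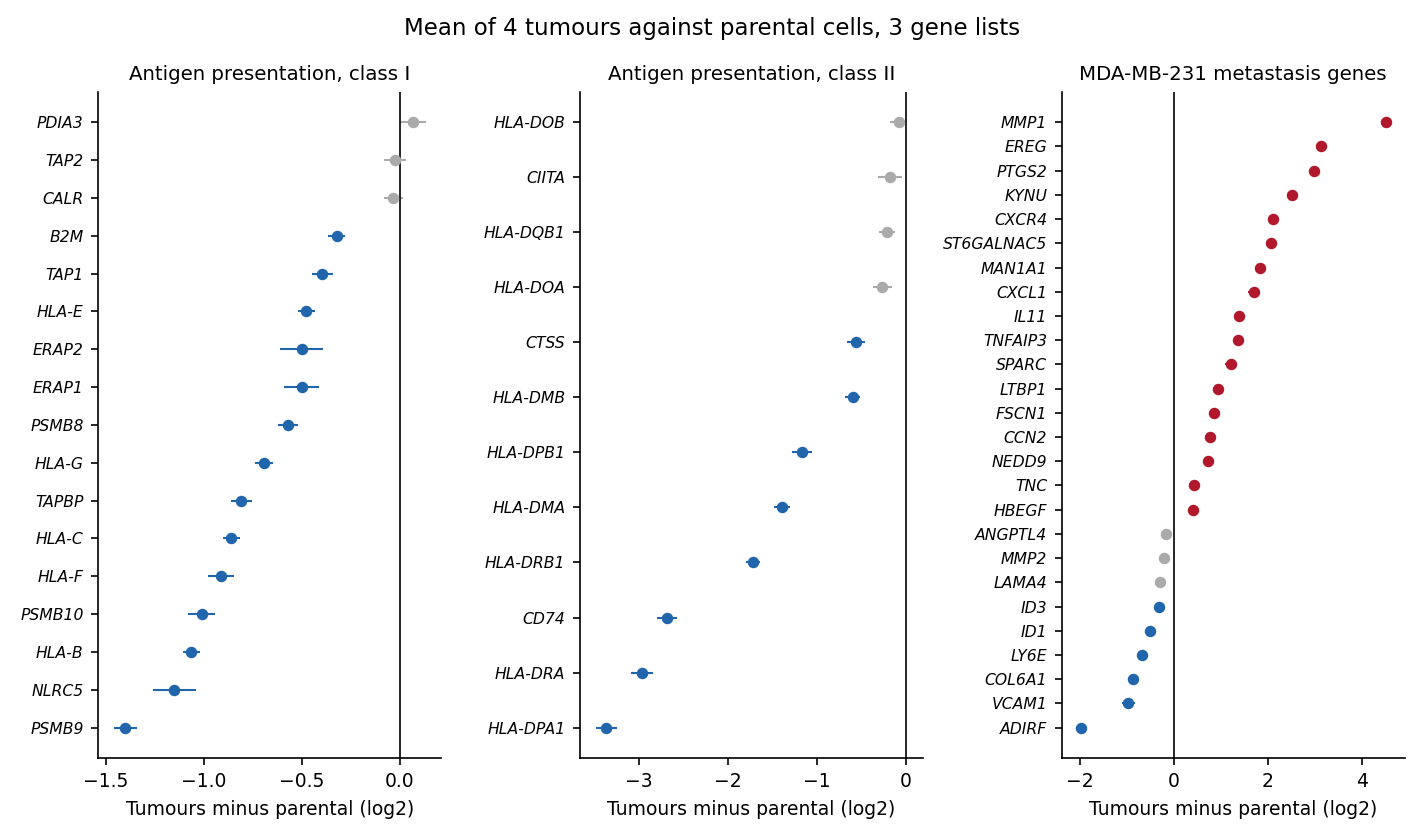
Mean log2 difference of the 4 tumours from parental cells (horizontal axes) for the measured genes of 3 lists (vertical axes), with bars for the SE and colours for genes called higher (red), called lower (blue) or not called (grey). Of the class I genes 14 of 17 and of the class II genes 8 of 12 were called lower, and 17 of 26 metastasis genes were called higher.

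The remaining 25 lists did not pass camera, with adjusted p-values of 0.0647 to 0.915. Without the filter on low values 14 lists passed, 9 higher and 5 lower. Those gained were all higher, namely YAP and TEAD targets (adjusted p = 0.0126), p53 targets (0.0232), caspases and the apoptosome, IAP proteins and antagonists, and hypoxia and glycolysis (0.0475 each). Without parental replicate 1 it was 12 lists, 6 and 6, with YAP and TEAD targets and caspases gained (0.0319 each), and YAP and TEAD targets were also gained without T2 replicate 1 (0.0441). Drug efflux transporters passed as lower with centred medians (0.0411) and with the mean over probe sets (0.0453), endothelial markers as higher with repeated quantile normalisation (0.0342). Each pair of counts given next is of genes called higher and lower over all genes, with the pair adjusted over the list alone in brackets. The IAP proteins and antagonists had 3 and 1 of 8 (3 and 1), led by the IAP-cleaving protease HTRA2 (0.54). Caspases and the apoptosome had 6 and 1 of 14 (7 and 1), with CASP4 at 1.40. Death ligands and receptors had 6 and 3 of 14 (7 and 4), with TNFSF15 at 1.42 beside TNFSF10. For the BCL2 family the counts were 4 and 1 of 20 (4 and 1), with BAX at -0.61. The TNF receptor complex had 6 and 5 of 27 (6 and 5), with the NF-kB inhibitor TNFAIP3 at 1.36 and the receptor TNFRSF1B at -1.34. EGFR ligands had 3 and 1 of 5 (3 and 1), with TGFA at -0.64. Receptor tyrosine kinases had 6 and 9 of 36 (6 and 9), with PTK7 at 0.87, and the LRIG family 0 and 2 of 3 (0 and 2), with LRIG2 at -0.37. TGF-beta targets had 6 and 6 of 17 (6 and 7), with the activin subunit INHBA at 2.54 and ID2 at 2.20. For Wnt targets the counts were 4 and 2 of 13 (6 and 3), with LEF1 at 1.31, and for YAP and TEAD targets 12 and 4 of 23 (12 and 4), with CRIM1 at 1.04.

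Proliferation genes went both ways, 15 and 10 of 45 (17 and 11 adjusted over the list alone), with CCNE1 at -0.55. So did mesenchymal markers, 11 and 11 of 31 (11 and 11), with the actin-binding TAGLN at 2.59 and the calcium-binding S100A4 at -2.25. Epithelial markers had 5 and 7 of 26 (5 and 8), with CLDN1 at 1.21. Breast stem and luminal markers had 3 and 4 of 13 (3 and 4), with CD24 at 1.71, and cancer-testis antigens 2 and 3 of 10 (2 and 3), with MAGEC1 at 1.75. Hypoxia and glycolysis genes were called in 16 and 4 of 36 (17 and 5), with ADM at 1.07, and p53 targets in 10 and 3 of 22 (10 and 4), with GDF15 at 1.29. The unfolded protein and amino acid response had 11 and 5 of 26 (12 and 5), with ASNS at -0.76. Cholesterol synthesis had 9 and 3 of 18 (10 and 3), with EBP at -1.01, and drug efflux transporters 1 and 5 of 10 (2 and 6), with ABCA2 at -0.59. Of markers of other cells, endothelial genes had 6 and 0 of 11 (6 and 0), with ESAM at 1.29 and ROBO4 at 0.82. PECAM1 (-0.18 ± 0.09) and VWF (-0.16 ± 0.10), also endothelial, were not called. Fibroblasts and pericytes had 0 and 2 of 7 (0 and 0), with COL1A2 at -0.38. Blood and lymphocytes had 1 and 1 of 6 (1 and 1), with CD3D at 0.34, and adipocytes and muscle 0 and 2 of 8 (0 and 2), with MB at -0.71. The median and the mean differed in sign for the TNF receptor complex (-0.01 and 0.01), epithelial markers (-0.12 and 0.03), cancer-testis antigens (-0.02 and 0.21) and breast stem and luminal markers (-0.07 and 0.05). Camera followed the mean for cancer-testis antigens and the median for the other 3.

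Each tumour was also set against parental cells to see how far regrown tumours share their changes. T2 was marked by MMP1 (4.76 ± 0.07), WDR72 (4.44 ± 0.13) and BCL2A1 (4.25 ± 0.14) above and HLA-DPA1 (-3.77 ± 0.15), SERPINA1 (-3.59 ± 0.15) and HLA-DRA (-3.46 ± 0.15) below. In T3 the secreted proteoglycan gene ESM1 (6.17 ± 0.15), SFTA3 (6.07 ± 0.15) and PTGS2 (5.11 ± 0.12) rose most. Parental means of these 3 genes were 4.32, 3.20 and 4.03, near background, so the sizes of their rises are uncertain, as are those of BCL2A1 (parental mean 3.67) and BEX5 (4.48). HLA-DPA1 (-3.76 ± 0.15), SERPINA1 (-3.73 ± 0.15) and COXFA4L3 (-3.45 ± 0.09) fell most there. T6 showed WDR72 (4.15 ± 0.13), MMP1 (4.12 ± 0.07) and EREG (3.83 ± 0.14) higher and SERPINA1 (-4.01 ± 0.15), CEMIP (-3.17 ± 0.15) and OLFML2A (-2.99 ± 0.11) lower. In T8 MMP1 (4.33 ± 0.07), KISS1 (4.16 ± 0.07) and BEX5 (4.07 ± 0.12) were higher and CEMIP (-3.62 ± 0.15), CYP1B1 (-3.35 ± 0.08) and HLA-DPA1 (-3.22 ± 0.15) lower. All of these had an adjusted p of at most 1.24e-09, each over 2 arrays against 2. With the mean over probe sets WDR72 stood at 1.76 in T2 and 1.55 in T6, EREG at 2.45 in T6 and SERPINA1 at -2.02, -2.17 and -2.24 in T2, T3 and T6. CEMIP then stood at -2.10 in T6 and -2.27 in T8, and without the less specific probe sets at -1.04 and -0.91. All of these calls held (adjusted p of at most 4.95e-05).

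By counts, 2609 genes were higher and 2319 lower in T2, 3294 and 2359 in T3, 3097 and 2052 in T6 and 4285 and 2247 in T8. Repeated quantile normalisation gave 2800 and 2905 in T2, 3021 and 3090 in T3, 2729 and 3018 in T6 and 3117 and 3333 in T8. Centred medians gave 2312 and 1646 in T2, 3276 and 1595 in T3, 3115 and 1242 in T6 and 4914 and 1292 in T8. In T8 that scaling moved the median of all genes from 0.03 to 0.13. Without T6 replicate 1, T6 replicate 2 or parental replicate 2 the T6 count of 5149 fell to 3255, 3299 and 3422. In all 4 tumours 1324 genes were called higher and 808 lower, against 34.3 and 7.58 for independent lists. In 100 simulations without effect but with shared parental arrays, which carried only the spread between arrays, both numbers were 0. No line differed in them, so they test array noise alone and not whether changes of single tumours overlap. A repeated quantile normalisation gave 1242 and 1288, and centred medians 1242 and 490. The log2 changes of pairs of tumours correlated over genes, which are not independent replicates, at 0.589 to 0.861 (mean 0.749, simulated 0.50). Their mean covariance was 0.142 beside 0.00646 simulated, and 56.3% of genes had the same sign in all 4 tumours beside 40.0% simulated. Part of the excess in calls may come from the shared parental arrays. When 1 parental array was set against 2 tumours and the other against the other 2, a split chosen after seeing the data, 850 to 963 genes were higher and 558 to 579 lower in all 4. These are the ranges over the 6 ways to do so, with 1 parental array assumed to vary like the other lines. Each tumour then had 1 parental array in place of 2, which by itself lowers counts and correlations. The drop therefore does not measure what sharing the parental arrays adds. Neither the simulations nor this split remove changes peculiar to the single parental line, which all 4 comparisons share. Tumours set against different parental arrays correlated at 0.505 to 0.819 (mean 0.672), with a mean covariance of 0.133.

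The tumours of a class were compared to see how alike they were. Between the resistant tumours, T2 exceeded T3 in TRBC1 (2.98 ± 0.09), a T cell receptor constant gene, WDR72 (2.98 ± 0.13) and DCDC2 (2.96 ± 0.13). T3 exceeded T2 in SFTA3 (-6.05 ± 0.15), ESM1 (-5.93 ± 0.15) and the cancer-testis antigen gene MAGEC1 (-4.18 ± 0.12). ESM1 stood at 4.56 in T2 and 10.5 in T3. XIAP, the IAP that binds and blocks caspases directly, differed by -0.98 ± 0.13 between T2 and T3 (adjusted p = 2.22e-05), and all 5 further probe sets went the same way. Between the sensitive tumours, DCDC2 (2.57 ± 0.13), the nucleoside transporter SLC28A2 (2.03 ± 0.20) and WDR72 (1.95 ± 0.13) were higher in T6. ESM1 (-3.38 ± 0.15), MAGEC1 (-2.64 ± 0.12) and BEX5 (-2.56 ± 0.12) were higher in T8. Each of these 12 largest differences had an adjusted p of at most 1.78e-05 over 2 arrays against 2. The mean over probe sets lowered TRBC1 to 1.81, WDR72 to 1.26 and DCDC2 to 1.56 for T2 minus T3. For T6 minus T8 it lowered DCDC2 to 1.31, SLC28A2 to 1.04 and WDR72 to 0.86, each still called (adjusted p of at most 0.000794). T2 and T3 differed in 4594 genes (2069 higher in T2, 2525 lower) and T6 and T8 in 2253 (696 and 1557). After repeated quantile normalisation the split was 2780 to 2517 for T2 minus T3 and 1293 to 1385 for T6 minus T8. Leaving out T6 replicate 1, T6 replicate 2, T8 replicate 1 or T8 replicate 2 gave 940, 1077, 1124 and 1037 genes between T6 and T8.

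The fixed genes cover the drug's targets, the TNF receptor pathway and receptor tyrosine kinases. BIRC2, the cIAP1 gene and a direct target of Smac mimetics, was higher in the tumours by 0.32 ± 0.05 (adjusted p = 4.56e-05). It rose by 0.53 in T2, 0.26 in T6, 0.31 in T8 and 0.19 in T3, and with repeated quantile normalisation by 0.19 in T8 and 0.10 in T3 (adjusted p = 0.000649 and 0.0312). The T3 call ended without parental replicate 2 (adjusted p = 0.110) or T3 replicate 2 (0.135, in a range of 0.0078 to 0.135 over alternatives). T2 exceeded T3 in BIRC2 by 0.34 ± 0.06, and the response difference of 0.07 ± 0.04 was not called. It was called only with repeated quantile normalisation (adjusted p = 0.0281, in a range up to 0.719 over alternatives). TNF lay near background (4.70 to 5.04 per line) and was called in none of these comparisons. LRIG1 fell in T2 (-0.97 ± 0.14) and T3 (-0.69 ± 0.14) but was not called in T6 (0.06) or T8 (0.29). With the mean over its probe sets both calls ended (adjusted p = 0.107 and 0.370, the highest of their alternatives). Over the 4 tumours LRIG1 stood at -0.33 ± 0.11 (adjusted p = 0.0299). That call ended without parental replicate 1 (0.273), T6 replicate 2 (0.0592) or T8 replicate 2 (0.0519), in a range of 0.00768 to 0.670. XIAP stood at -0.43 ± 0.13 in T2 (adjusted p = 0.0153), not called without parental replicate 1 (0.185) or T2 replicate 1 (0.0865). In T3 XIAP was at 0.56 ± 0.13 (adjusted p = 0.00258), not called without T3 replicate 2 (0.0509). It was at 0.22 in T6 (0.192, but 0.0161 without parental replicate 1). In T8 it was at 0.37 (0.0254), not called without parental replicate 2 (0.307) or T8 replicate 1 (0.209). Its response difference of -0.23 ± 0.09 (0.0788) was called without T3 replicate 2 (0.0376), parental replicate 1 (0.0294) or parental replicate 2 (0.0295). Over the 4 tumours XIAP stood at 0.18 (0.160, but 0.0108 without parental replicate 1). Its adjusted p ranged over alternatives from 0.000992 to 0.185 in T2, 0.000155 to 0.0509 in T3, 0.0161 to 0.931 in T6 and 0.00154 to 0.307 in T8. For the response that range was 0.0211 to 0.300 and for the 4 tumours 0.0108 to 0.932. Centred medians ended the calls of XIAP in T2 (0.0520) and of LRIG1 over the 4 tumours (0.102), and repeated quantile normalisation that of XIAP in T8 (0.106). With the mean over probe sets LRIG1 stood at -0.04 over the 4 tumours (0.670), while the response difference of XIAP was called (0.0211). Without a trend BIRC2 in T3 (0.0795), LRIG1 over the 4 tumours (0.0519) and XIAP in T2 (0.0545) and T8 (0.0688) were not called. XIAP stood at 0.57 in T8 without parental replicate 1 (0.00154) and at 0.36 in T3 without parental replicate 2 (0.0393).

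CASP8, the initiator caspase of death receptors, was at -0.30 ± 0.09 in resistant against sensitive tumours (adjusted p = 0.0283). That call ended with repeated quantile normalisation (0.0518) and without T2 replicate 1 (0.0974), T3 replicate 1 (0.101), T6 replicate 1 (0.111), T6 replicate 2 (0.0614) or T8 replicate 1 (0.127), in a range of 0.00921 to 0.649. Without a trend CASP8 was not called either (0.0657), and with the mean over its probe sets it stood at -0.05 (0.649). Against parental cells CASP8 stood at -0.41 in T3 (0.0162), not called without parental replicate 1 (0.195) or T3 replicate 1 (0.0914). T2 minus T3 was 0.38 (0.0289), not called without T2 replicate 2 (0.188), T3 replicate 1 (0.142) or T3 replicate 2 (0.0615). The adjusted p of CASP8 ranged over alternatives from 0.00168 to 0.195 in T3 and from 0.00610 to 0.274 for T2 minus T3. TNFRSF1A, the main TNF receptor, was at -0.24 ± 0.06 in T3 (0.00669, but 0.159 with centred medians). Its T2 minus T3 was 0.23 (0.0112), not called without T2 replicate 2 (0.0642) or T3 replicate 1 (0.0661). For TNFRSF1A the ranges were 7.45e-05 to 0.159 and 0.000265 to 0.149. CFLAR, the caspase inhibitor FLIP, stood at -0.22 in T2 (0.0235), not called without parental replicate 1 (0.177) or T2 replicate 1 (0.123). It was at -0.22 in T8 (0.0222), not called without parental replicate 1 (0.155), T8 replicate 1 (0.0848) or T8 replicate 2 (0.107). For T6 minus T8 it was at 0.28 (0.0138), not called without T6 replicate 1 or 2 (0.0612 and 0.147) or T8 replicate 1 or 2 (0.0786 and 0.108). For CFLAR the ranges were 0.00435 to 0.186 in T2, 0.000149 to 0.370 in T8 and 0.000634 to 0.804 for T6 minus T8. Centred medians ended the calls of CASP8 in T3 (0.0710) and for T2 minus T3 (0.0869) and of TNFRSF1A for T2 minus T3 (0.149). They also ended those of CFLAR in T2 (0.186), in T8 (0.370) and for T6 minus T8 (0.137). The mean over probe sets ended the calls of CASP8 in T3 (0.0663) and for T2 minus T3 (0.274) and of CFLAR in T8 (0.0536) and for T6 minus T8 (0.804). CASP8 for T2 minus T3 was not called without a trend (0.0669) or with array weights (0.0554), nor CFLAR in T2 without a trend (0.0514).

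EGFR was higher in the resistant tumours by 0.25 ± 0.05 (adjusted p = 0.00592, but 0.0671 with centred medians, in a range of 0.000143 to 0.286). Most of it came from T3, at 0.63 ± 0.08 from parental cells (1.23e-05) and -0.53 ± 0.08 for T2 minus T3. Averaged over its probe sets these were 0.37 (0.00355) and -0.25 (0.0335), the highest p of their alternatives. In T8 EGFR stood at 0.27 (0.00897), not called with repeated quantile normalisation (0.0938) or without T8 replicate 1 (0.117). T6 minus T8 was -0.32 (0.00963), not called without T6 replicate 1 (0.0798), T6 replicate 2 (0.0672) or T8 replicate 1 (0.132). The adjusted p of EGFR ranged over alternatives from 0.00369 to 0.117 in T8 and from 0.000634 to 0.132 for T6 minus T8. Over the 4 tumours EGFR rose by 0.24 ± 0.06 (0.00502), or by 0.14 with repeated quantile normalisation (0.0149, in a range of 0.00118 to 0.0416). ERBB2 stood at -0.23 ± 0.06 there (0.0049), not called with centred medians (0.103) or without parental replicate 2 (0.0820), in a range of 0.000613 to 0.679. It was lowest in T3 (-0.43 ± 0.07), with 0.35 ± 0.07 for T2 minus T3. With the mean over its probe sets both calls ended (adjusted p = 0.197 and 0.246, the highest of their alternatives). In T8 ERBB2 was at -0.26 (0.0102), not called with centred medians (0.203) or without parental replicate 2 (0.0765), T8 replicate 1 (0.0583) or T8 replicate 2 (0.0580), in a range of 0.000566 to 0.457. Averaging over probe sets ended the calls of EGFR for the response (0.286) and for T6 minus T8 (0.0697) and of ERBB2 over the 4 tumours (0.679) and in T8 (0.457). EGFR for T6 minus T8 was not called without a trend either (0.0505). MET was higher in T2 than in parental cells by 0.36 ± 0.08 and than in T3 by 0.48 ± 0.08. Without T2 replicate 2 the former was 0.23 (0.0327, in a range of 0.000164 to 0.0353). No other comparison of the 10 measured fixed genes was called as reported, but alternatives called some. Repeated quantile normalisation called TNFRSF1A over the 4 tumours (-0.20, 0.000710), in T6 (-0.17, 0.0123) and in T8 (-0.26, 0.000777). It also called CFLAR over the 4 tumours (-0.20, 0.00252) and in T3 (-0.18, 0.0201), MET in T3 (-0.25, 0.00115), ERBB2 in T6 (-0.25, 0.0200) and CASP8 for T6 minus T8 (0.32, 0.0399). CFLAR over the 4 tumours was called with the mean over probe sets (-0.14, 0.0488), CASP8 for T6 minus T8 with array weights (0.28, 0.0416) and CASP8 in T6 without parental replicate 1 (0.40, 0.0212). The highest adjusted p over alternatives was 0.659, 0.865 and 0.992 for these 3 of TNFRSF1A, 0.625 and 0.790 for the 2 of CFLAR, 0.780 for MET, 0.571 for ERBB2 and 0.585 and 0.908 for CASP8. With repeated quantile normalisation CFLAR stood at -0.36 (0.000149) and ERBB2 at -0.42 (0.000566) in T8. With the 8 tumour arrays as independent samples LRIG1 was called for the response (0.0433, in a range of 0.0433 to 0.9998 over alternatives of the fit with the tumour as replicate).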

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

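The tests in this part were chosen after the results were seen, apart from the 35 splits of the 8 tumour arrays and the shares in and outside neighbouring stretches.

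Genes of the text that were called in opposite directions against parental cells in the tumours of a response class, with the difference itself tested in limma, were singled out; in all, 443 genes met the first condition in T2 and T3 and 52 in T6 and T8. TRBC1 was higher in T2 (1.07) and lower in T3 (-1.91), a difference of 2.98 (adjusted p = 9.42e-12). MAGEC1 was lower in T2 (-0.47) and higher in T3 (3.71), a difference of -4.18 (8.21e-12). XIAP was lower in T2 (-0.43) and higher in T3 (0.56), a difference of -0.98 (2.22e-05); the call in T2 ended without parental replicate 1 or T2 replicate 1 (0.185 and 0.0865) and that in T3 without T3 replicate 2 (0.0509). TTLL11 was lower in T6 (-0.27) and higher in T8 (0.64), a difference of -0.91 (2.70e-05). Probe sets with no or several gene names, which the comparisons above do not use, also moved: 1335 of 5515 tested differed between the 4 tumours and parental cells (702 higher, 633 lower, from -3.02 to 2.55).

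More genes separated T2 and T6 from T3 and T8 than resistant from sensitive tumours. With the tumour as replicate the response split gave 0 genes, that other split 114 and the remaining one, T2 and T8 against T3 and T6, 0; over arrays they gave 2837, 4996 and 1691. The 4 tumours allow 3 splits, too few for a share under 0.05. With the 8 arrays as independent samples the response split gave 12 genes and the other 2540, and these 2 alone of 35 splits gave 12 or more; the 32 splits that part the arrays of a tumour gave 0, and since arrays of a tumour are near-duplicates, only 3 splits inform here too. A count so much larger points to a structure of the tumours other than their response, though this split had already been seen on the principal components and is the largest of only 3.

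For T2 and T6 against T3 and T8, fixed shares of a T2-like and a T3-like population as its whole source could not be decided. Outside neighbouring stretches, the share of the way from T2 to T3 was compared between genes higher in T2 and genes higher in T3. In T8 it differed by 0.197 between the former (0.723, 95% bootstrap interval 0.679 to 0.750) and the latter (0.527, 0.445 to 0.623). These intervals lay apart, which met the rule set against fixed shares in T8, within the limits given below. In T6 the difference was 0.102 and the intervals overlapped (0.229 to 0.385 and 0.122 to 0.233). Fixed shares predict equal values only where the signal is linear in the amount of RNA, and an array compresses differences near background. The intervals also treat genes of the same line means as independent. Gains or losses of chromosome segments may contribute, because T2 minus T3 ran together over neighbouring genes in the GRCh38.p14 order. The largest median over 41 neighbours was 0.986, against 0.248 at most in 1000 random orders, and XIAP lies in such a stretch. For T2 and T6 against T3 and T8 it was 0.668 beside 0.210. Resistant minus sensitive tumours (0.243 beside 0.180), T6 minus T8 (0.425 beside 0.217) and the 4 tumours minus parental cells (0.504 beside 0.314) also exceeded every random order, though with smaller medians. Running together is therefore not particular to the split of T2 and T6 from T3 and T8. Unequal shares of tumour cell populations as a part of it stay open, since shares from neighbouring stretches and from other genes differed by 0.0305 at most, yet that test cannot tell a mixture from separate clones with intermediate levels. RNA quality was not excluded either: GAPDH 3' minus 5' values of T2 and T6 (0.13 to 0.15) lay below those of T3 and T8 (0.16 to 0.21), by -0.0551 on average, while those of ACTB overlapped.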

How the results depend on the processing

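All alternatives were chosen before the data were examined except the exchanged replicate numbers and the split of the parental arrays. Counts of calls stayed within 1.5 times of the reported ones in 216 recomputations and moved further in 40. Of the named genes' values 3110 kept direction and side of the threshold, 80 lost a call, 19 gained one, 58 changed sign without being called in either fit and 1 reversed: TENM3 stood at -0.12 (adjusted p = 0.511) for the tumours against parental cells when probe sets that can match several transcripts were left out, since a different probe set then stands for the gene. Named genes without a tested value under an alternative, such as LRIG1 without the less specific probe sets, are not counted among these values. Of the list calls 224 held, 61 were lost and none turned. Asking for a change of log2 1, which by construction lowers counts, gave 32 genes for the response over arrays, 397 for the 4 tumours against parental cells, 521, 553, 422 and 494 for T2, T3, T6 and T8, 429 for T2 minus T3, 74 for T6 minus T8 and 201 shared by all 4 tumours. For the response with the tumour as replicate, the count of 0 became 4 with the line as a random block (estimated correlation 0.508), 12 with arrays as independent samples, 23 without tumour T2 and 1 without tumour T3, which leave 1 resistant tumour and take the spread from the sensitive pair; the cause was not tested. It stayed 0 without T6 or T8, with the parental line among the sensitive, with only the 4 tumours and without any 1 array. Lists called for the response were 4, and 2 with repeated quantile normalisation, 0 with the mean over probe sets, 0 without the less specific probe sets, 0 with estimated correlation, 1 with fry and 0 to 5 without 1 array. Those for the tumours against parental cells were 10, and 6 with the filter at log2 6, 5 without the less specific probe sets, 0 with estimated correlation, 14 without the filter, 27 with fry, which does not compare a list with other genes, and 7 to 12 without 1 array. T6 minus T8 gave 1377 genes with centred medians, 1492 without the less specific probe sets and 3831 with array weights in place of 2253; the cause was not tested. Leaving out 1 array, which reduces the arrays of a line to 1 assumed to vary like the others, gave 1389 to 3535 genes for the response over arrays, 4099 to 6877 for the 4 tumours against parental cells, 3905 to 4974, 4084 to 6015, 3255 to 5585 and 4361 to 6915 for T2, T3, T6 and T8, 3449 to 4753 for T2 minus T3, 940 to 2638 for T6 minus T8 and 1475 to 2297 for genes shared by the tumours.

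With the replicate number as a block, counts were 2500 for the response over arrays, 6051 for the 4 tumours and 2124 for T6 minus T8, and no count moved by over 1.5 times. The calls of CASP8 for the response (adjusted p = 0.0512) and for T2 minus T3 (0.0511), of LRIG1 for the 4 tumours (0.0555) and of the NF-kB targets (0.0680) ended. Among the named genes and the lists, no other call over arrays changed. Deviations of same-numbered arrays from their line means correlated at 0.502 between T2 and T3 and at 0.146 to 0.308 among the parental line, T6 and T8, but at -0.387 to -0.137 between these 2 sets. The numbers as labelled therefore did not pair all lines, while a batch that runs across the numbers in T2 and T3 stays open. Array medians showed the same division. Replicate 1 had the higher median in T2 (5.55 against 5.48) and T3 (5.52 against 5.45). It had the lower one in parental cells (5.52 against 5.57), T6 (5.47 against 5.49) and T8 (5.43 against 5.46). A remaining difference in array scale could not be told apart from a batch here. The numbers of T2 and T3 were then exchanged, an assignment taken from the correlations of these deviations. That block gave 4856 genes for the response over arrays and 7724, 6130 and 6924 for the 4 tumours, T2 and T3 against parental cells.

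Signal over background limits what can be read for genes near log2 5 or below, such as TNF, CDH5, PLCB4, SMIM31, NRK, PTGS2, BCL2A1, ESM1, SFTA3, DCDC2 and BEX5 in the lower of the groups compared, whose differences an array compresses. The 2 arrays of a line deviate equally from their mean, so array weights differed between lines (0.642 in T2 to 1.75 in T6) but not within a line, and the weights name no outlying array.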

Other observations

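The test of the chromosome segment was set before its result was seen, and the tests of other cells' markers after it.

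Several members of the gene lists differed between resistant and sensitive tumours over arrays although camera did not call their lists, and are named here after their values were seen; fry called the lists of HLA-DPA1 (class II) and S100A4 (mesenchymal markers), with an adjusted p of 0.0274 each. The death receptor gene FAS (0.65 ± 0.08), the BH3-only gene PMAIP1 (0.45 ± 0.05) and the NF-kB inhibitor TNFAIP3 (0.46 ± 0.06) were higher in the resistant tumours, together with EGR1 (0.62 ± 0.06) and the cancer-testis antigen gene MAGEA6 (1.18 ± 0.17). Lower were the pentraxin PTX3 (-0.96 ± 0.09), the calcium-binding S100A4 (-0.82 ± 0.05), HLA-DPA1 (-0.80 ± 0.11), the luminal transcription factor GATA3 (-0.70 ± 0.09), the growth factor-binding IGFBP3 (-0.56 ± 0.06) and the EGFR ligand EREG (-0.51 ± 0.10). Of 14 death ligands and receptors FAS alone was higher, 4 were lower and 9 not called (camera adjusted p = 0.811), and of 20 genes of the BCL2 family PMAIP1 alone was higher, 5 were lower and 14 not called (0.571). NF-kB targets went both ways, 4 higher and 11 lower of 33 (camera adjusted p = 0.471), as did the TNF receptor complex with 1 and 7 of 27 (0.394) and p53 targets with 6 and 3 of 22 (0.321). With the tumour as replicate none of these genes was called (adjusted p of at least 0.894).

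Between the resistant tumours, differences ran together over stretches of neighbouring genes. In 105 genes from ZMYM3 to CT83 the median of T2 minus T3 was -0.66, in the stretch from TEX13B to DUSP9, which includes XIAP, it was -0.54, and in 71 genes from PLCXD1 to MBTPS2 it was 0.59. The other 3 stretches were LINC01365 to FHIP1A (-0.51, 66 genes), SLC7A11 to PLRG1 (-0.52, 52 genes) and IBTK to RTN4IP1 (-0.38, 57 genes), and 78.1% to 93.0% of the genes of a stretch lay on the same side. Picking stretches by a running median of T2 minus T3 favours such shares. The stretches also take in neighbours on either side of the picked genes and can overlap. Between resistant and sensitive tumours the medians of these 6 stretches, picked on T2 minus T3, were -0.15 to 0.10, but that comparison also ran together elsewhere, with a largest median over 41 neighbours of 0.243 beside 0.180 at most in 1000 random orders. Of the 400 genes that differed most between T2 and T3, T6 and T8 both lay between them in 74%, beside 13% to 42.75% for the other pairs taken as ends. Genes picked for a large gap tend to have other lines within it, and T2 and T3 were the least correlated pair of tumours (0.983). The share therefore describes their spacing and tests nothing.

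The fall of class II genes in all 4 tumours (median -0.88) was set against 2 technical or structural sources. Loss of the whole stretch from HLA-F to HLA-DPB1 was argued against by 72 other genes in it. Their median change was -0.0457 (95% bootstrap interval -0.107 to -0.0103), with 10 called higher and 15 lower. A smaller loss, of the class II part alone, was not tested. The parental sample was a cultured cell line. Median marker levels there went against macrophages and B lymphocytes, without meeting the bounds set to exclude them. The median level of 16 macrophage markers there lay at -2.95 from that of 13 class II genes (7.46), which goes against macrophages. Of these markers 9 stood under log2 5, among them LYZ (4.43) and TYROBP (4.01), beside HLA-DRA at 9.20. LAPTM5 (10.7) and AIF1 (6.74) stood higher. The 95% bootstrap interval (-4.61 to -0.985) reached past the -1 set as the bound, and LAPTM5 (-0.61), CSF1R (-0.68) and ITGAM (-0.40) fell. For B lymphocytes, MS4A1 (4.49, changed by 0.07), PTPRC (4.05, -0.04) and CD79A (7.42, -0.19) did not follow HLA-DRA (-2.96). That goes against B lymphocytes, but 3 markers (-2.98) were too few to exclude them. No biological explanation was tested.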
